A study of Homo sapiens with 2 samples.

How the data were processed

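HUVECs from microfluidic devices perfused with healthy red blood cells (hRBC) or with 5% dehydrated red blood cells in healthy ones (5% pdRBC) were profiled with 10x Genomics 5′ version 2 single-cell RNA sequencing. Per the labels' protocols, the cells were taken from the devices, strained, freed of red cells with a lysis buffer and captured at once. The deposited files hold raw UMI counts per gene and barcode, which the authors made with Cell Ranger 7.0.0, per the file headers and the submitters' processing notes. The genome build was GRCh38, per the submitters' processing notes, and the gene annotation release and any further filter are not given in the sources used here. Whether counting used strand is not given either, so overlapping and antisense genes are uncertain, as are families of similar genes. No deposited barcode has fewer than 500 UMIs, so cells were called before deposit. Of 36601 genes in the files, 34616 (94.6%) matched GENCODE release 29 by identifier, from which gene positions and transcript lengths were taken. XIST and the Y-linked genes, 105 in all, were left out of the variable genes, lists, measured genes and tables, though their UMIs remain in each library's total.

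A barcode was kept as a cell at 1000 or more UMIs, 500 or more genes and at most 20% of UMIs from mitochondrial genes, a filter set before the data were examined, since the labels state none. Kept cells of both libraries were clustered together with Scanpy 1.11.5: counts were scaled per cell and log-transformed, and 2000 variable genes, 30 principal components, 15 neighbours and Leiden clustering (python-igraph 0.11.9) at resolution 0.5 with seed 0 were used. No batch integration was applied, since library and treatment coincide. A cluster was named endothelial-like if at least 3 fixed endothelial markers had 3 or more UMIs, unless markers of another type led it or its cells were shallow for their library with no endothelial marker among its 10 leading genes. Shallow means that the cells' UMIs had a median under 1/3 of their own library's median. The 2 clusters left unnamed lay just below this, at 0.324 (cluster 7) and 0.330 (cluster 12). At resolution 1.0 a cluster that ANO2 and MECOM led, as they do cluster 7, lay at 0.384 and was named endothelial-like. A cluster was called cycling if at least 3 cycling markers were among its 20 leading genes. The details of this scoring, as opposed to the markers, were set after the data were seen. Scrublet, run per library, marked 1 of 2555 hRBC and 5 of 1601 5% pdRBC cells as doublets; with so few calls doublets cannot be considered removed, and all cells were left in.

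UMIs were summed per library over the endothelial-like cells, to 13291477 for hRBC and 15960416 for 5% pdRBC, and divided by that total to give CPM. A fold is the CPM of 5% pdRBC over hRBC with 0.5 UMIs added to each sum, and a gene is measured at 100 or more UMIs over both libraries. The 95% interval of a fold is the exact Clopper-Pearson interval of the gene's UMIs split between the libraries, and intervals of shares are exact binomial ones. All intervals cover counting error only: they hold neither the spread between devices or cultures nor that between cells. A count of 0 allows up to 3 counts, which is 0.226 CPM for hRBC and 0.188 CPM for 5% pdRBC. With 1 library per group no p-value was computed, since cells are not replicates.

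Of each of 37 gene lists fixed before the data were examined, the median log2 fold of the measured members is given with the 95% range of medians over 1000 Poisson draws of the members' UMIs. Its percentile among 10000 random lists of the same size, matched on mean expression in 20 bins, describes these libraries and is no test of the treatment. The lists cover leukocyte adhesion and chemokines, NF-kB, interferon, laminar and disturbed flow, YAP/TAZ, immediate early, heat shock, unfolded protein, heme and oxidant, metallothionein, hypoxia, cholesterol, S phase, G2 and M phase, coagulation, angiogenesis, junction, mesenchymal, matrix, actin, p53, mechanosensitive, glycocalyx, nuclear and mitochondrial respiration, ribosomal protein and long nuclear RNA genes. Markers of erythroid, T and NK, B, monocyte, neutrophil, platelet, fibroblast and mural, epithelial and lymphatic cells complete them. Named genes are the 12 with the largest fold higher and the 12 with the largest fold lower among measured genes at 20 or more CPM in 1 library with an interval leaving out 1, without mitochondrial, ribosomal protein, hemoglobin, clone-named and LINC genes. To these come up to 4 members of each list with the largest folds, and 16 endothelial genes named in advance. Members with small folds given for contrast, and genes marked as such in the text, were chosen after their values were seen. For shares of cells with a UMI, each cell was thinned to 2000 UMIs without replacement.

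The fold, its interval and the list percentile were tested on simulated counts drawn for 10923 genes from the real means and totals, with 200 genes changed. At planted folds of 4 and 8, 100% of 49 genes each were at least 2-fold different, of 50 genes planted at exactly 2-fold 56% were, and of 50 at 1.5-fold 2%. Of 10725 unchanged genes 0 reached 2-fold, and the interval held the true value for 95.7%. Of 200 random lists of unchanged genes, 11 lay outside percentiles 2.5 to 97.5. The simulated counts were independent Poisson draws, as the interval assumes, without spread between cells or devices or shared expression within a list. They check the computation only and not how often real libraries would differ.

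The alternatives were other cell filters (all deposited barcodes, or at least 2000 UMIs and 1000 genes with at most 10% mitochondrial), all kept cells, no doublets, no cycling cluster, edgeR 4.0.16 TMM factors, 2 other scalings, the mean of per-cell CPM, thinned cells, gene minimums of 20 and 500 UMIs, 5 UMIs added in place of 0.5, and Leiden resolution 1.0. For the 2 other cell filters the cells were clustered and named anew, and only those in clusters named endothelial-like were summed. These were 1878 hRBC and 1510 5% pdRBC barcodes out of all deposited ones, and 1353 and 1534 with the stricter filter. The alternative of all deposited barcodes thus summed fewer hRBC barcodes than the 2545 of the main setting. It cannot show what adding all low-UMI barcodes would do. Cells of 5000 or more UMIs were added as an alternative after the data were seen. Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, anndata 0.12.19, scikit-learn 1.9.0 and Matplotlib 3.10.9, and R 4.3.3, were used.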

Results

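The data are single-cell transcriptomes of human umbilical vein endothelial cells (HUVECs), primary cells grown for about 48 hours to a confluent lining of microfluidic devices with channels of 50 µm. The lined channels were then perfused for 4 hours with red blood cells. In the hRBC group all red cells were healthy. In the 5% pdRBC group, 5% of them had been dehydrated with nystatin and sucrose to a mean corpuscular hemoglobin concentration of 40 to 42 g/dL, which makes the cells stiffer, as many red cells are in sickle cell disease. Each group is 1 library of 5′ single-cell RNA, so differences between the groups have no replicate check, and no test or p-value is given. The hRBC library held 3858 barcodes with 14321939 unique molecular identifiers (UMIs, each a counted RNA molecule), with a median of 1381 UMIs per barcode (500 to 44616). In the 5% pdRBC library 1635 barcodes held 16158876 UMIs, with a median of 9425 (523 to 38876). After the cell filter 2555 and 1601 cells remained, with medians of 2175 and 9566 UMIs, 1273 and 3367 genes, and 2.17% and 1.85% of UMIs from mitochondrial genes. Of the hRBC barcodes, 1303 (33.8%, with 6.89% of the UMIs) did not pass the filter, against 34 (2.08%, with 0.191% of the UMIs) in the 5% pdRBC library.

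**Figure D1:**
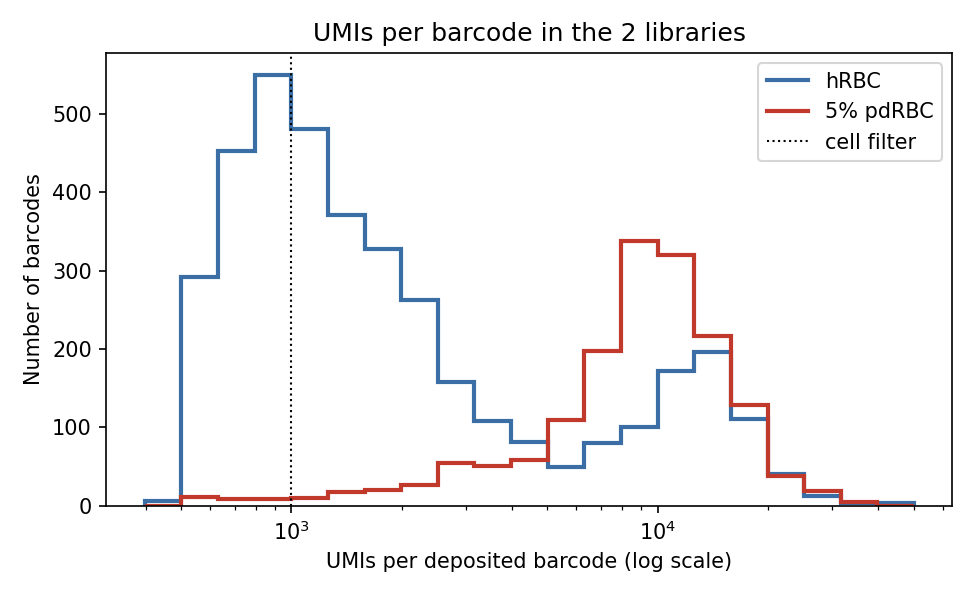
UMIs per deposited barcode (horizontal axis, log scale) against the number of barcodes (vertical axis) in the hRBC library (blue) and the 5% pdRBC library (red), with the minimum of 1000 UMIs as a dotted line. Most hRBC barcodes lie to the left of 3000 UMIs (74.5%), and few 5% pdRBC barcodes do (8.50%).

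Nearly all cells lay in clusters that expressed endothelial genes. Of the hRBC cells 2545 (99.6%, exact binomial 95% interval 99.3 to 99.8) and of the 5% pdRBC cells 1549 (96.8%, 95.8 to 97.6) fell in clusters named endothelial-like from PECAM1, CDH5, VWF, CLDN5, ERG and further markers. These shares cover counting error only and depend on the cell filter and on how whole clusters are named: with all deposited barcodes they were 48.7% and 92.4%, and at a finer clustering 100% in both. The 48.7% does not mean that the other hRBC barcodes lacked endothelial genes. With a median of 1381 and a lowest count of 500 UMIs, a cluster of hRBC barcodes alone could not be shallow there. Which rule left them unnamed was not examined. PECAM1 stood at 1013 CPM in the hRBC barcodes that the main filter left out, against 809 CPM in kept hRBC cells. In the main clustering the other 10 and 52 cells lay in clusters 7 and 12, left unnamed because their UMI counts were low for their library and no endothelial marker led them. Both expressed endothelial markers all the same (9 and 8 of the 10 detected). A cluster of hRBC cells alone could not be unnamed as shallow, since the library median was 2175 UMIs and the minimum 1000. The rule therefore weighs mostly on the 5% pdRBC share. By cells, cluster 1 held the largest part of the hRBC class (1028 cells, median over both libraries 1555 UMIs), and clusters 2 and 3 most of the 5% pdRBC class (563 and 490 cells). By UMIs, clusters 2 and 3 held most of both classes. Genes of stress or inflammation led some of the named clusters: EGR1, FOSB, KLF4 and ATF3 led cluster 3, DDIT3, TRIB3 and CXCL8 cluster 6, CXCL1, PTX3 and CCL2 cluster 9, CXCL2, CXCL1 and CXCL8 cluster 10, and PTX3 cluster 11. Clusters 9, 10 and 11 held 32, 24 and 22 hRBC cells and 0 5% pdRBC cells, and what sets these small groups apart was not tested. Cluster 5 was led by UBE2C and MKI67 and was called cycling, and cluster 8 was led by MKI67 too.

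No cluster was led by markers of another cell type. HBB, the beta chain of hemoglobin, gave 12 UMIs in the hRBC cells and 0 in the 5% pdRBC cells, whose floor of 3 counts is 0.188 CPM (UMIs scaled to a common library total). None of the B cell or neutrophil markers was measured, that is, reached 100 UMIs over both libraries. IL7R and IL32 were the measured T and NK cell markers (median log2 fold -0.15 (-0.34 to 0.03)), CD68 the monocyte marker (-0.01), and GNG11 and MYL9 the platelet markers (-0.02 (-0.08 to 0.05)). BPGM and SLC25A37 were the measured erythroid genes, with a median of 0.10 (-0.00443 to 0.20). Of the fibroblast and mural genes TAGLN, PDGFRA and RGS5 were measured (-0.18 (-0.49 to -0.12)), and FLT4 of the lymphatic genes (0.46 (0.06 to 0.86)). The measured epithelial genes were keratins, with a median of -0.51 (-0.61 to -0.41) (-0.55 to -0.24 across the alternatives): KRT19 was 2.07-fold (1.53 to 2.83) lower, KRT18 1.42-fold (1.33 to 1.53) lower and KRT8 1.12-fold (0.945 to 1.32) lower with 5% pdRBC.

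The comparison asks whether a small share of stiff red cells alters the endothelium they flow over, the question the series title frames as inflammation. Across 11001 measured genes the libraries were similar. With 5% pdRBC, 28 genes (0.255%) were at least 2-fold higher and 26 (0.236%) at least 2-fold lower, each with a counting interval that left out 1, and 10713 (97.4%) differed by less than 1.5-fold. The median log2 fold was 0.01, and Pearson's correlation of log2 CPM across genes, which are not independent replicates, was 0.992. These counts depend on the gene minimum and the weight of each cell: they were 182 and 131 at a minimum of 20 UMIs, 10 and 9 at 500 UMIs, 44 and 54 with every cell weighted equally, and 14 and 13 with each cell thinned to 2000 UMIs. A stricter cell filter gave 31 and 15, and cells of 5000 or more UMIs, an alternative added after seeing the data, 41 and 14, so that the near balance of the counts did not hold there.

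Immediate early genes, which are transcribed within minutes of a stimulus such as shear stress or growth factors, were the group furthest above the rest. EGR1, a zinc-finger transcription factor, was 7.98-fold (6.63 to 9.75) higher with 5% pdRBC, at 9.03 and 72.3 CPM. FOS, an AP-1 subunit, was 3.98-fold (3.55 to 4.48) higher, its partner JUN 1.98-fold (1.87 to 2.10) and FOSB 2.47-fold (2.24 to 2.73). ZFP36, which destabilises inflammatory mRNAs, was 3.37-fold (2.93 to 3.91) higher, the stress-inducible factor ATF3 2.90-fold (2.61 to 3.23), and the nuclear receptor NR4A2 3.87-fold (2.54 to 6.32). Of 17 measured members, 9 were at least 1.5-fold higher and 0 lower, and the list's median log2 fold of 0.63 (0.54 to 0.74) lay above those of all 10000 expression-matched random lists (percentile 100). FOSL1, SRF, IER5 and BTG2 were close to equal, with log2 folds of -0.000101, 0.000296, 0.04 and -0.03. Other genes with large folds included GEM, a small GTPase induced by stimulation (2.42-fold higher), NFATC2, a calcium-regulated transcription factor (2.09-fold), the pseudokinase gene TRIB1 (2.08-fold) and the long noncoding RNA LUCAT1 (2.06-fold). In GRCh38 coordinates EGR1 spans 138465490 to 138469315 on the plus strand of chromosome 5, and FOS 75278774 to 75282230 on the plus strand of chromosome 14.

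Genes of leukocyte recruitment were higher in part. CXCL8, the neutrophil chemokine interleukin-8, was 1.70-fold (1.54 to 1.88) higher with 5% pdRBC, the cytokine IL6 1.73-fold (1.41 to 2.14), and the chemokine CXCL2 1.89-fold (1.49 to 2.43). SELE, which codes for E-selectin, was 1.66-fold (1.20 to 2.33) higher on 57 and 114 UMIs. ICAM1, the ligand of leukocyte integrins, was 1.34-fold (1.17 to 1.54) higher and CCL2, the monocyte chemokine, 1.19-fold (1.10 to 1.28) higher. CXCL1, another neutrophil chemokine, went the other way at 2.24-fold (1.94 to 2.58) lower, and ICAM2 and IL32 had log2 folds of -0.07 and -0.03. The list's median was 0.50 (0.29 to 0.63), at percentile 100, with 4 of 10 measured members at least 1.5-fold higher and 1 lower. VCAM1 (2 and 8 UMIs) and SELP (7 and 6 UMIs), adhesion receptors of activated endothelium, were too sparse to measure, so that a difference in them was not detectable at this depth. The list's position depends on choices of the analysis: with every cell counted equally its median was -0.00488, and with a minimum of 500 UMIs per gene, which leaves out CXCL2, CXCL3, IL6 and SELE, it was 0.11. With equal weight the log2 folds of CXCL2, CCL2, CXCL8 and ICAM1 were -0.20, -0.06, 0.15 and 0.20, against 0.92, 0.25, 0.76 and 0.42 in the sums, and that of SELE was 1.72 with equal weight and 0.24 in cells of 5000 or more UMIs, against 0.73. In cells of 5000 or more UMIs and with the stricter cell filter the log2 fold of CXCL2 was 1.90 in both and that of CXCL8 0.95 and 1.07, and CXCL1 ran from -0.75 with the stricter filter to -1.91 with equal weight.

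Among NF-kB feedback genes and targets, PTGS2, the inducible cyclooxygenase, was 1.56-fold (1.49 to 1.64) higher and NFKBIZ, an inducible regulator of NF-kB, 1.63-fold (1.45 to 1.83) higher. BIRC3, an inhibitor of apoptosis, was 1.47-fold (1.04 to 2.11) lower and NFKB2 1.41-fold (1.04 to 1.93) lower. The median of 17 measured members, 0.07 (-0.04 to 0.17), lay at percentile 88, with 2 members at least 1.5-fold higher and 0 lower. For the interferon response the median over 8 measured members was -0.000876 (-0.08 to 0.10), at percentile 42.4, with the mean slightly positive at 0.03; GBP1, an interferon-induced GTPase, was 1.14-fold (0.776 to 1.67) lower.

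**Figure D2:**
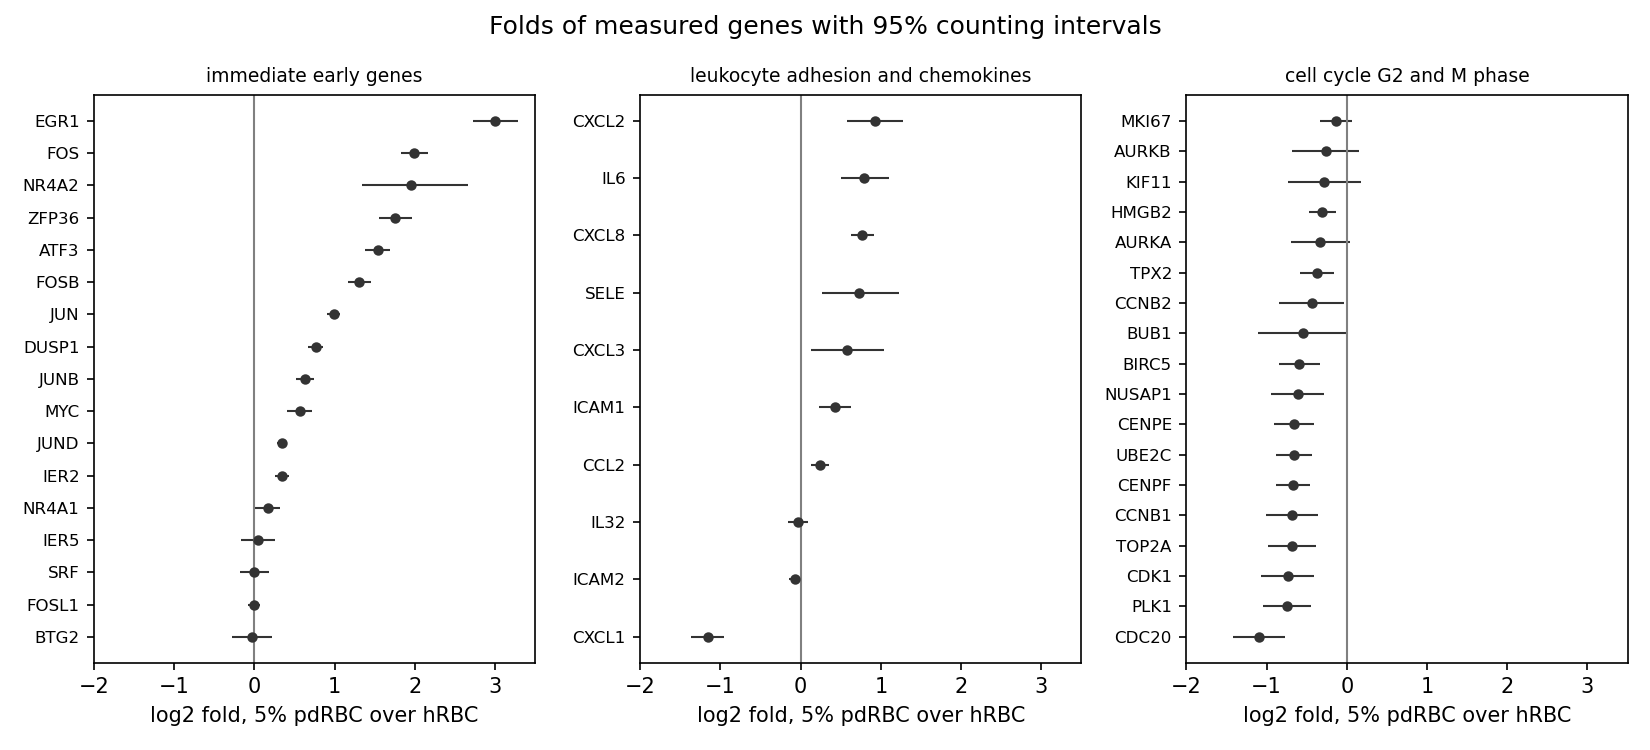
Log2 fold of 5% pdRBC over hRBC (horizontal axis) for each measured gene (vertical axis) of the immediate early, leukocyte adhesion and chemokine, and G2 and M phase lists, with bars for the 95% counting interval and 1 library per group. EGR1 lies furthest to the right at 3.00, CXCL1 is the chemokine to the left at -1.16, and all 18 genes of the G2 and M phase list lie left of 0, from -0.13 for MKI67 to -1.09 for CDC20.

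Flow-responsive genes did not differ as 1 group. KLF4, a transcription factor that laminar shear induces, was 2.04-fold (1.88 to 2.20) higher with 5% pdRBC, with 1719 of its 2178 UMIs there in cluster 3, which it leads, whereas KLF2, which shear induces in the same way, was level at 1.02-fold (0.964 to 1.09). ADM, the vasodilator peptide adrenomedullin, was 1.88-fold (1.60 to 2.23) higher and CYP1A1 1.70-fold (1.31 to 2.23) higher. NOS3, the endothelial nitric oxide synthase, was 1.40-fold (1.28 to 1.52) lower, the angiopoietin receptor gene TEK 1.36-fold (1.27 to 1.47) lower and ALPL 2.57-fold (1.68 to 4.07) lower. Over 13 measured members of the laminar flow list the median was 0.01 (-0.08 to 0.04) (percentile 61.1), with 4 at least 1.5-fold higher and 2 lower. THBD, the thrombin receptor thrombomodulin, was level at 1.05-fold (0.941 to 1.18).

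In the list for disturbed or low flow, ANGPT2, a destabiliser of vessels, was 1.29-fold (1.18 to 1.42) higher, BMP4 1.20-fold (1.01 to 1.43) higher and EDN1, the vasoconstrictor endothelin, 1.07-fold (1.04 to 1.11) higher, while ANKRD1 was 1.31-fold (1.26 to 1.35) lower. The median of 0.10 (0.08 to 0.14) over 11 members lay at percentile 98.8, with 0 members past 1.5-fold. YAP/TAZ targets, which respond to cell stretch and stiffness, had a median of 0.08 (0.05 to 0.12) at percentile 97.6; F3 was 1.38-fold (1.09 to 1.76) higher and AJUBA 1.31-fold (1.09 to 1.58) higher. Both medians were small and took the opposite sign, -0.01 each, when every cell was weighted equally. PIEZO1, a channel opened by membrane tension, was 1.22-fold (1.13 to 1.31) higher, and KCNJ2, a flow-sensitive potassium channel, 1.59-fold (1.21 to 2.11) higher, while KDR, a receptor of the shear sensor complex, was 1.19-fold (1.12 to 1.25) lower. The list of mechanosensitive channels and receptors had a median of 0.02 (-0.07 to 0.08) (percentile 68.7, 1 of 15 members at least 1.5-fold higher and 7 with a negative log2 fold).

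Genes of cell division were lower with 5% pdRBC. CDC20, an activator of the anaphase-promoting complex, was 2.13-fold (1.71 to 2.68) lower, the mitotic kinases PLK1 and CDK1 1.67-fold (1.36 to 2.06) and 1.67-fold (1.33 to 2.10) lower, and TOP2A, which untangles chromosomes, 1.60-fold (1.30 to 1.98) lower. All 18 measured genes of G2 and M phase had a negative log2 fold and 10 were at least 1.5-fold lower, with a median of -0.60 (-0.67 to -0.46) below those of all 10000 random lists. MKI67 was the least different, at a log2 fold of -0.13 (-0.33 to 0.06). S phase genes had a median of -0.16 (-0.30 to -0.07) at percentile 0.33, which depended on the choices (-0.06 in cells of 5000 or more UMIs, -0.09 in the named clusters of all barcodes, -0.44 at a minimum of 500 UMIs and -0.49 with thinned cells): RRM2, which makes deoxynucleotides, was 1.53-fold (1.32 to 1.77) lower, and TYMS 1.36-fold (1.19 to 1.55) lower. The replication histone gene HIST1H4C was 2.33-fold (2.05 to 2.67) lower. Cluster 5, led by mitotic genes, held 139 of 2545 hRBC and 113 of 1549 5% pdRBC cells, but 13.1% and 8.30% of the UMIs. The order of its size by cells is thus the opposite of that by UMIs, but only at this resolution. At resolution 1.0 a cluster of 143 hRBC and 125 5% pdRBC cells was called cycling, and so was a shallow cluster of 276 and 9 (median 1325 UMIs). By cells the hRBC library there had the larger cycling share. Without cluster 5 the G2 and M phase median was -0.86, so that the difference did not lie in that cluster alone. The cells that remained still included cluster 8, led by MKI67 (26 hRBC and 20 5% pdRBC cells). Cluster 5 with its 139 hRBC cells also cannot hold all 276 of the shallow cycling cluster. The value therefore does not show lower mitotic genes outside cycling cells.

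Heat shock, heme and endoplasmic reticulum stress genes were close to level as groups. FTH1 and FTL, the ferritin chains that store iron, were 1.23-fold (1.23 to 1.24) and 1.29-fold (1.29 to 1.30) higher, and HMOX1, which degrades heme, 1.16-fold (1.13 to 1.19) higher. The heme and oxidant list had a median of 0.05 (0.03 to 0.08) over 15 genes, at percentile 95.2. For 14 heat shock genes the median was -0.02 (-0.05 to 0.03), at percentile 39, with a positive mean of 0.04; HSPA1A was 1.35-fold (1.03 to 1.79) higher, which is uncertain because HSPA1A and HSPA1B are near-identical. DDIT3, the stress factor CHOP, was 1.55-fold (1.29 to 1.87) higher and HSPA5, the main chaperone of the endoplasmic reticulum, 1.21-fold (1.15 to 1.27) lower, in an unfolded protein list with a median of -0.06 (-0.13 to -0.02) (percentile 7.52). The metallothionein list, of which MT1E, MT1X, MT2A and the zinc exporter gene SLC30A1 were measured, had a median of -0.36 (-0.51 to -0.27) at percentile 0.09. MT1E was 1.77-fold (1.58 to 1.99) lower and MT2A 1.28-fold (1.26 to 1.29) lower. The log2 fold of SLC30A1 was -0.36 (-0.58 to -0.14), and that of MT1X, -0.21 (-0.60 to 0.17), had an interval that held 0; the metallothioneins are again a family of similar genes. VEGFA, the angiogenic growth factor, was 1.42-fold (1.08 to 1.89) higher and LDHA, of glycolysis, 1.26-fold (1.21 to 1.31) lower. The hypoxia and glycolysis median was -0.06 (-0.18 to 0.08), at percentile 15, with a mean of the other sign at 0.04.

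In coagulation and fibrinolysis, the plasminogen activator genes PLAU and PLAT were 1.71-fold (1.38 to 2.13) and 1.48-fold (1.24 to 1.77) lower, and TFPI, an inhibitor of tissue factor, 1.19-fold (1.13 to 1.26) higher. VWF, the platelet-tethering factor, was 1.08-fold (1.04 to 1.12) higher. The median of 0.01 (-0.10 to 0.07) lay at percentile 59.4, with a mean of -0.06. CLDN5, a tight junction gene, was 1.34-fold (1.20 to 1.49) higher and PECAM1 1.16-fold (1.12 to 1.19) lower in a junction and identity list with a median of -0.04 (-0.09 to -0.01) (percentile 24.4). For angiogenesis and tip cell genes the median was -0.05 (-0.10 to -0.01) (percentile 12.1), NRP1 being 1.24-fold (1.17 to 1.32) higher and UNC5B 1.35-fold (1.11 to 1.63) lower. Matrix and protease genes had a median of 0.03 (-0.00389 to 0.08) (percentile 88.9), with the collagenase gene MMP1 1.25-fold (1.22 to 1.28) higher. CD44, the hyaluronan receptor, was 1.56-fold (1.33 to 1.82) lower in a glycocalyx list with a median of -0.00349 (-0.09 to 0.10) (percentile 52.9).

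Mesenchymal transition genes had a median of -0.14 (-0.19 to -0.02) at percentile 1.91, with TAGLN 1.38-fold (1.12 to 1.72) lower and SNAI1, a repressor of cadherin genes, 1.37-fold (1.24 to 1.51) higher, and the median was 0.04 at a minimum of 500 UMIs per gene. Actin cytoskeleton genes stood at -0.09 (-0.11 to -0.06) (percentile 5.11), with ACTN4 1.22-fold (1.16 to 1.29) lower. The p53 list was lower, at -0.15 (-0.18 to -0.06) (percentile 0.04): GADD45A, a growth arrest gene, was 1.25-fold (1.14 to 1.37) lower and MDM2, the p53 ligase, 1.20-fold (1.11 to 1.30) lower. Cholesterol synthesis genes had a median of -0.12 (-0.16 to -0.04) (percentile 0.13), and MVD was 1.25-fold (1.13 to 1.39) lower. Across the alternatives the p53 median ran from -0.20 to -0.09 and the cholesterol median from -0.21 to -0.08. None of the genes of these lists was past 1.5-fold.

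Nuclear genes of mitochondrial respiration were mostly lower by a small amount. UQCR10, of respiratory complex III, was 1.42-fold (1.343 to 1.498) lower, COX6C and COX7C, of cytochrome oxidase, 1.36-fold (1.29 to 1.43) and 1.32-fold (1.27 to 1.38) lower, and ATP5F1E, of ATP synthase, 1.27-fold (1.24 to 1.30) lower. Of 16 measured members 14 had a negative log2 fold and none passed 1.5-fold (COX4I1 and COX5A were at 0.04 and 0.03), and the median of -0.25 (-0.28 to -0.22) lay below those of all 10000 random lists. The mitochondrial genome list, 12 protein-coding genes without MT-ND6, had a median of -0.15 (-0.16 to -0.12) (percentile 1.94), with MT-ND3 1.54-fold (1.49 to 1.59) lower. That median shrank to -0.0202 in cells of 5000 or more UMIs and to -0.0249 with the stricter cell filter, and was -0.0746 in the named clusters of all barcodes and -0.29 with every cell weighted equally. Cytosolic ribosomal protein genes were level, at -0.02 (-0.03 to -0.01) (percentile 68.8). The list labelled long nuclear RNAs holds MALAT1, NEAT1, KCNQ1OT1, MEG3, SNHG1, SNHG5, GAS5 and NORAD, and where these RNAs lie in the cell was not measured. Its median was 0.13 (0.01 to 0.16) (percentile 99.1, 0.07 to 0.16 across the alternatives). NEAT1, the scaffold of paraspeckles, was 1.20-fold (1.18 to 1.22) higher and SNHG5 1.22-fold (1.15 to 1.29) lower. Of 8 members 3 had a negative log2 fold, and the summed CPM was level, at 10735 for hRBC and 10810 for 5% pdRBC.

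**Figure D3:**
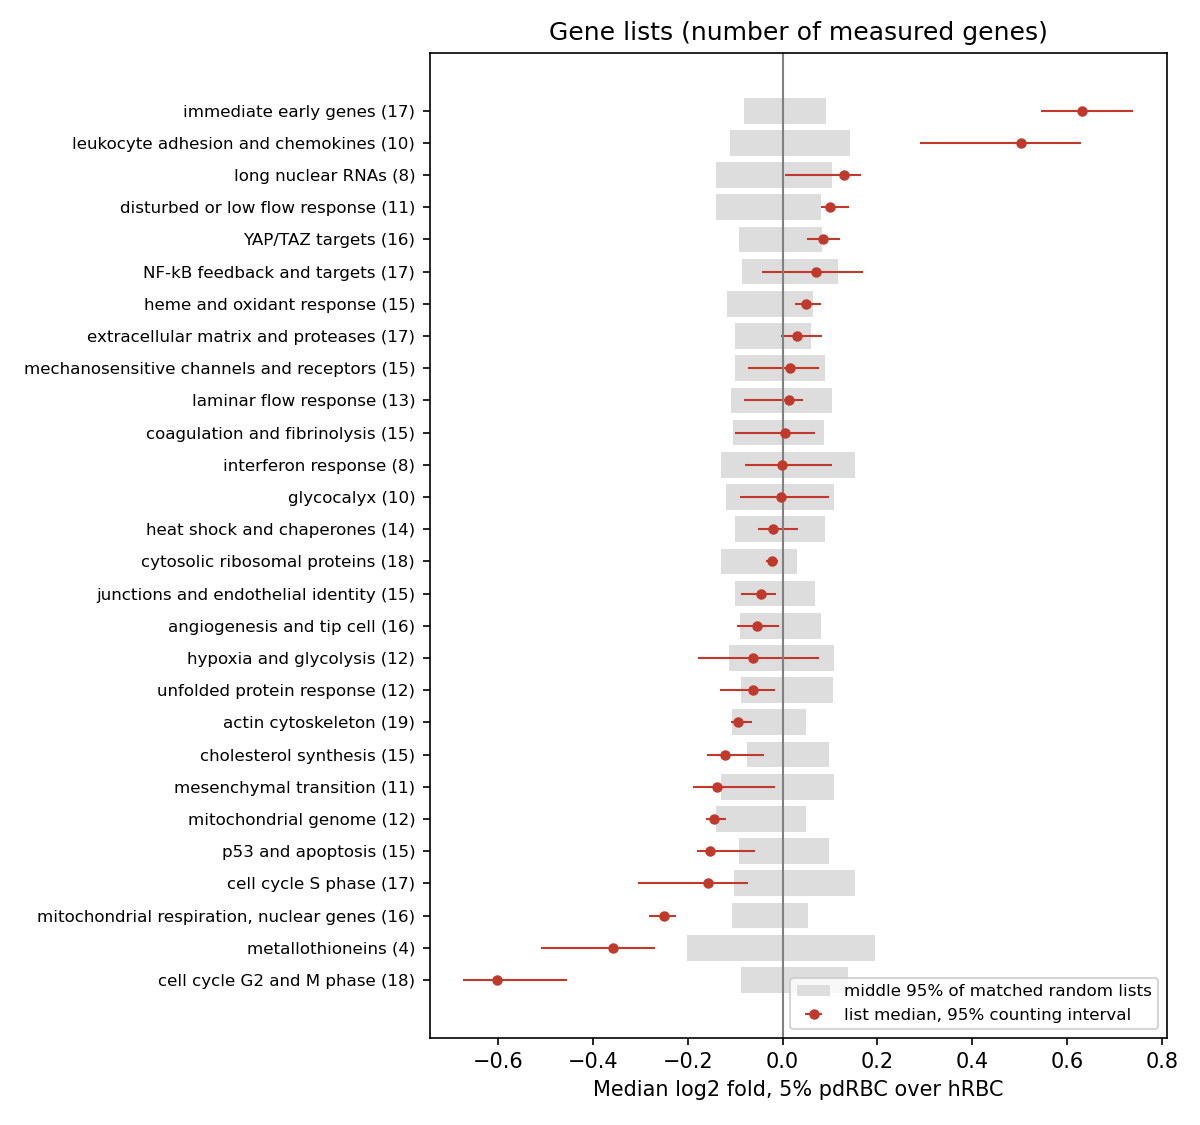
Median log2 fold of 5% pdRBC over hRBC (horizontal axis) for each fixed list with 4 or more measured genes (vertical axis, number measured in parentheses), with the 95% counting interval as a red bar and the middle 95% of 10000 expression-matched random lists as a grey bar. Immediate early genes (0.63) and leukocyte adhesion and chemokine genes (0.50) lie right of their grey bars, and G2 and M phase genes (-0.60) lie furthest to the left.

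Several genes with large folds lower belonged to no fixed list. LINGO1, which codes for a leucine-rich repeat membrane protein known from neurons, was 7.67-fold (6.76 to 8.77) lower with 5% pdRBC, at 130 and 16.9 CPM. SLC26A3, a chloride and bicarbonate exchanger, was 7.05-fold (5.53 to 9.20) lower, at 32.9 and 4.64 CPM. HIST1H1E, a linker histone gene, was 2.84-fold (2.36 to 3.45) lower, but its log2 fold was -0.04 in cells of 5000 or more UMIs, so that its difference lay in the shallow cells. CRIP1, a LIM domain protein gene, was 2.36-fold (2.10 to 2.66) lower, S100A2 2.07-fold (1.75 to 2.47), the neuropeptide gene NPW 2.02-fold (1.76 to 2.33) and TNFRSF6B, a decoy receptor for Fas ligand, 1.90-fold (1.63 to 2.23). ADAMTSL1, the activin antagonist FST and C19orf33 were 1.83-fold, 1.83-fold and 1.77-fold lower. LINGO1 spans 77613027 to 77820900 on the minus strand of chromosome 15 and SLC26A3 107765467 to 107803225 on the minus strand of chromosome 7, in GRCh38.

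Shares of cells with a UMI were compared after thinning each endothelial-like cell to 2000 UMIs, which left out 1180 hRBC and 35 5% pdRBC cells and kept 1365 and 1514. EGR1 had a UMI in 1.10% (0.616 to 1.81) of hRBC and 8.26% (6.92 to 9.76) of 5% pdRBC cells, and FOS in 4.62% (3.56 to 5.87) and 12.2% (10.5 to 13.9). CXCL8 was seen in 3.74% (2.79 to 4.88) and 7.13% (5.89 to 8.55), CCL2 in 7.47% (6.13 to 8.998) and 9.97% (8.51 to 11.6), ICAM1 in 3.66% (2.73 to 4.80) and 5.15% (4.09 to 6.39), and SELE in 0.513% (0.206 to 1.05) and 0.793% (0.410 to 1.38). MKI67 was seen in 5.35% (4.22 to 6.68) and 3.43% (2.58 to 4.48), and TOP2A in 2.34% (1.61 to 3.29) and 1.25% (0.757 to 1.95). KLF2, at 24.0% (21.7 to 26.3) and 22.8% (20.7 to 24.98), and HMOX1, at 57.6% (54.9 to 60.2) and 55.7% (53.1 to 58.2), are given with no order because their shares go against the CPM. The intervals of both libraries overlapped for these and for CCL2, ICAM1, SELE, MKI67 and TOP2A. LINGO1 was seen in 20% (17.9 to 22.2) and 3.90% (2.98 to 5.00), and SLC26A3 in 4.98% (3.89 to 6.27) and 0.859% (0.458 to 1.46). VCAM1 was seen in 0 hRBC cells, which allows a share of up to 0.220%, and in 0.132% (0.0160 to 0.476) of 5% pdRBC cells. HBB was seen in 0.0733% (0.00185 to 0.407) of hRBC cells and 0 of the 5% pdRBC cells, which allows up to 0.198%.

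Without thinning, the shares were 3.10% and 18.6% for EGR1, 8.25% and 25.8% for FOS, 7.31% and 17.5% for CXCL8, 15.2% and 24.5% for CCL2, 7.54% and 16.1% for ICAM1, and 0.668% and 2.07% for SELE. They were 8.25% and 9.23% for MKI67, 4.60% and 5.04% for TOP2A, 36.0% and 58.7% for KLF2, and 65.0% and 84.1% for HMOX1. For LINGO1 they were 32.2% and 15.2%, for SLC26A3 13.2% and 4.52%, for VCAM1 0.0393% and 0.452%, and for HBB 0.118% and 0%. These carry the gap in depth, with medians of 2157 and 9697 UMIs per endothelial-like cell, and the thinned hRBC share describes the deeper part of its library. No other cell type was found from which a background share could be taken. With cells thinned to 1000 UMIs, where no cell is left out, the intervals of CXCL8, at 4.13% (3.39 to 4.97) and 4.91% (3.88 to 6.10), overlapped, and CCL2 was at 6.99% and 5.87%. EGR1, FOS, LINGO1 and SLC26A3 were added to this set after their folds were seen.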

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

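All tests in this part were chosen only after the result was seen. HBB, the hemoglobin beta chain, gave 837 UMIs in hRBC barcodes that the cell filter left out, a signal in data outside the comparisons and above the limit that 0 counts allow in the 5% pdRBC library. It lay in 8 barcodes, 757 of the UMIs in a single one with 806 UMIs and 33 genes, of which HBB was 93.9%, and kept hRBC cells held 12 further UMIs. PECAM1, an endothelial adhesion gene, gave 1000 UMIs in the same left-out hRBC barcodes, or 1013 CPM against 809 CPM in the kept hRBC cells. In the 5% pdRBC library 3.25% of kept cells (52 cells, 2.44 to 4.24%) lay in the unnamed clusters, which the main comparison leaves out, against 0.391% (10 cells, 0.188 to 0.719%) in the hRBC library. In the same order, their median mitochondrial share was 9.32% and 7.56%, against 1.83% and 2.17% in the endothelial-like cells, and NEAT1, a nuclear RNA, took 1.27% and 1.85% of their UMIs against 0.232% and 0.193%. The rule that left these clusters unnamed turns on depth, and kept cells had medians of 2175 UMIs in hRBC and 9566 in 5% pdRBC. With a minimum of 1000 UMIs, a cluster of hRBC cells alone could not be unnamed as shallow. The rule names whole clusters, however, and does not set how the cells of each library fall into them. At resolution 1.0 the cluster that ANO2 and MECOM led was named, and it held 23 hRBC and 46 5% pdRBC cells. The cause of the difference between the 2 unnamed shares was not tested. With 1 library per group it is no result about the exposure.

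The hRBC library held many barcodes of few UMIs, 74.5% of them under 3000 against 8.50% in the 5% pdRBC library. Free RNA alone would give such barcodes 1 shared profile, yet the median variance of the 200 most abundant genes over that expected from 1 profile was 1.12 in barcodes of 500 to under 1000 UMIs and 1.22 in barcodes of 1000 to under 3000, above the highest of 100 draws from 1 profile, 1.00 and 1.01. Cells that lost their cytoplasm and kept their mitochondria were predicted to at least double the mitochondrial share, and the median was 1.34 times that of barcodes of 5000 or more UMIs (2.41% against 1.80%), which argues against this as the main source. A mixture of free RNA with damaged or small cells may remain, as may a larger number of barcodes called before deposit, and neither was tested. The exposure itself stays open and untested, since each library is the single one of its group.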

How the results depend on the processing

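The alternative of cells with 5000 or more UMIs was chosen only after the data were seen, as was the choice of the immediate early and the G2 and M phase medians as main results. Of 488 alternative values of list medians, 417 moved by less than their counting interval, 67 by more, and 4 took the opposite sign of a list outside the middle 95% of its random lists. Of 1977 values of named genes 1772 moved by less, 204 by more, and 1 took the opposite sign of a gene at least 1.5-fold different with an interval leaving out 1. Of 112 alternative shares of cells with a UMI, 63 moved past their interval. Most moves of list medians came with the mean of per-cell CPM (18 of 35 lists), thinned cells (15 of 34) and cells of 5000 or more UMIs (12 of 35). Of 14 lists outside the middle 95% of their random lists, 10 kept their sign under all 14 alternatives, and of 45 named genes at least 1.5-fold different 44 did under each alternative in which they were measured. Genes at least 2-fold higher and lower numbered 28 and 26. They numbered 44 and 54 with the mean of per-cell CPM, 14 and 13 with thinned cells, 182 and 131 at a minimum of 20 UMIs and 10 and 9 at 500, where more or fewer genes are tested. With the stricter filter they numbered 31 and 15, and in cells of 5000 or more UMIs 41 and 14. With the mean of per-cell CPM the leukocyte adhesion and chemokine median of 0.50 was -0.00488, the disturbed flow and YAP/TAZ medians were -0.0134 and -0.0102, the log2 fold of CXCL2 was -0.20, the immediate early median 0.52 and the G2 and M phase median -0.67. The adhesion and chemokine median was 0.23 with thinned cells and 0.11 at a minimum of 500 UMIs, at which the mesenchymal median was 0.0445. Without the cycling cluster the G2 and M phase median was -0.86. For these changes the cause was not tested. Across all alternatives the immediate early median ran from 0.52 to 0.70 and that of G2 and M phase from -0.86 to -0.50. The share named endothelial-like in hRBC and 5% pdRBC cells was 48.7% and 92.4% with all deposited barcodes, 98.6% and 99.5% with the stricter filter, and 100% in both at resolution 1.0. It turns on the naming of whole clusters, and which rule left the hRBC barcodes unnamed was not examined. Depth limits the hRBC library most, where 767 cells of 5000 or more UMIs (30.1%) gave 74.6% of the UMIs.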

Other observations

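The per-cluster values, the genes named in this and the next paragraph and all but 1 of the tests in this part were chosen only after the result was seen; the exception is the first length matching of the respiratory genes. Several genes below the 20 CPM minimum for naming had large folds. AMPD3, an AMP deaminase, was 6.12-fold (3.60 to 11.9) higher with 5% pdRBC, AADAC, an esterase, 5.43-fold (3.17 to 10.6), the semaphorin gene SEMA4A 4.46-fold (2.87 to 7.52) and the kinase gene TESK2 3.92-fold (2.73 to 5.93), on 14 to 34 hRBC UMIs each; an antisense gene overlaps AADAC, which makes its count uncertain. The EGR1-led cluster 3 held most 5% pdRBC UMIs of AMPD3, AADAC, SEMA4A and TESK2 (91, 80, 90 and 133). RASGEF1B, an exchange factor for Ras-family GTPases, was 6.16-fold (4.50 to 8.76) lower, CXCL12, a chemokine for CXCR4-bearing cells, 2.61-fold (2.02 to 3.42) lower and the growth factor gene IGF2 2.22-fold (1.79 to 2.78) lower. CSF2, the cytokine GM-CSF, had 20 and 67 UMIs, and CCL20, a chemokine, 40 and 18, both under the minimum for a fold.

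Folds were taken within each of the 5 endothelial-like clusters that held 100 or more cells of both libraries. LINGO1 was lower beyond its counting interval in 5 of 5 clusters (log2 folds -3.18 to -2.31), as were SLC26A3 (-3.33 to -2.37), CRIP1 (-2.52 to -0.73) and HIST1H4C (-1.78 to -0.55), and RASGEF1B was lower in 5, beyond its interval in 4. AMPD3, TESK2 and AADAC were each higher beyond their intervals in 1 cluster, cluster 3, and lower within them in 2. SEMA4A was higher beyond its interval in 2 and lower within it in 1. In cells thinned to 2000 UMIs the variance of LINGO1 over its mean was 1.11 and 1.03 in the hRBC and 5% pdRBC libraries, against 1 for Poisson counts. At means of 0.231 and 0.0403 UMIs per cell these values cannot show whether all cells expressed it. CXCL8 was higher beyond its interval in 4 clusters, up to a log2 fold of 3.68 in cluster 4, and 1 cluster, the low-UMI cluster 1, had -0.58 within its interval; its variance over mean was 2.22 and 3.48. FOS was higher in the same 4 clusters (variance over mean 1.35 and 2.09), and other immediate early genes were less even: JUN was higher beyond its interval in 4 clusters and lower in cluster 1 (-0.64), and ZFP36 higher in 2 and lower in cluster 1 (-1.18). CCL2 was higher beyond its interval in 4 clusters and lower in cluster 3 (-0.38), while CXCL1 was higher beyond its interval in 1 and lower beyond it in 3. ICAM1 was higher beyond its interval in clusters 2 and 3 and lower beyond it in cluster 4 (-0.66). The labels do not say whether a library is 1 device or several pooled, nor whether both libraries came from cells of 1 donor or 1 lot.

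Cluster 3, which EGR1, FOSB, KLF4 and ATF3 led, held 968 of the 1154 EGR1 UMIs of the 5% pdRBC library and 53 of the 120 of the hRBC library, so the EGR1 difference lay mostly in cells that these genes define. EGR1 was also higher beyond its interval in clusters 2, 4 and 5 (log2 folds 0.81, 1.67 and 1.82), and in cluster 1 it had 10 hRBC and 0 5% pdRBC UMIs. KLF4 was higher in clusters 3 and 5 only and lower in the other 3, and in cluster 2 FOSB and KLF4 were lower beyond their intervals (-0.99 and -0.38), as was ATF3 in cluster 1 (-1.24). FOSB and ATF3 were each higher beyond their intervals in 3 clusters. At resolution 1.0 a cluster led by EGR1, FOSB and ATF3 held 20 hRBC and 167 5% pdRBC cells, which restates the folds of its defining genes.

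Immediate early genes were higher with 5% pdRBC (median 0.63). Shallow barcodes of the hRBC library as the cause were argued against by cells of 5000 or more UMIs, where the median was 0.62. Without the cycling cluster the median was 0.70, but this cannot decide on a different weight of cycling cells. Leaving that cluster out did not remove the difference in cycling genes, since the G2 and M phase median was then -0.86. Handling after perfusion, which is known to induce these genes, may have differed between the libraries and cannot be told apart from the exposure, since each group has 1 library: the heat shock median of -0.0200 shows no shared shift of heat shock genes, but immediate early genes can be induced alone. A response of the endothelium to stiff red cells is the biological hypothesis, and it stays open.

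Nuclear genes of respiration were lower with 5% pdRBC (median -0.25), and many are short; random lists matched on longest transcript length and expression, a test written before its result was known, put them at percentile 0. Matching on the length of the principal transcript, added later, put them at percentile 0 with lengths in bins and 0.24 with the closest lengths (random median -0.07), and the mitochondrial transcripts at 5.97 and 14.6. Among abundant genes outside both lists, 8 with a principal transcript under 400 nt had a median of -0.41, 74 of 400 to 600 nt -0.18 and 943 of 2500 nt or more 0.01, so that part of the difference may go with length. Shallow hRBC barcodes were argued against by the median of -0.22 in cells of 5000 or more UMIs. A difference in respiration genes from the exposure stays open and untested.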
